A study of Homo sapiens with 4 samples.

How the data were processed

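RNA from Daoy cells, an established human medulloblastoma line, was sequenced in 4 libraries, 2 from cells stably expressing a control shRNA and 2 from cells stably expressing a PELP1 shRNA. Per the labels' protocols, the shRNAs were delivered by lentivirus, total RNA was prepared with a column kit and libraries were made with an Illumina TruSeq total RNA kit. Whether transcripts with a poly(A) tail were selected is not stated, so counts of histone and small nucleolar RNA genes, most of which have none, can depend on that step. The libraries were read as 50 bp single-end reads. Per the submitters' processing notes, reads were aligned to hg19 with TopHat2 2.0.8b and counted per gene with HTSeq. The HTSeq version, its strand setting and the gene annotation are not given in the sources used here. Reads of a gene and of an antisense partner that overlaps its exons therefore cannot be told apart.

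The deposited values were raw read counts per gene symbol, with no normalisation. Each file held 23228 gene rows and 5 rows that name no gene. Of those, only the rows for reads in no gene, ambiguous reads and reads aligned to more than 1 place held counts. Alignments that were not unique made up 30.82% and 30.71% of the file total in the control libraries and 29.38% and 29.57% in the PELP1 shRNA libraries. Reads in no gene made up 9.08%, 9.01%, 8.83% and 8.86%, and ambiguous reads 0.58% to 0.60%. These rows were left out of library sizes and tests. Genes with near-identical copies lose their shared reads to the row of alignments that were not unique, so their counts are partial. Mitochondrially encoded genes were not analysed here.

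Library sizes were 24052542 and 26629578 counts in genes for the control shRNA and 29221640 and 26760085 for the PELP1 shRNA. From 17641 to 17851 genes had at least 1 count. The 10 most abundant genes held 4.83% to 5.05% of the counts. Ratio intervals given for genes with few counts cover counting error only, since reads without molecular identifiers are not independent molecules.

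The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimation, TMM scaling and the filter filterByExpr, which kept 14972 genes. TMM factors ranged from 0.967 to 1.033. The model held an intercept and the shRNA group, p-values were two-sided, and the Benjamini-Hochberg false discovery rate (FDR) threshold was 0.05. Log2 fold changes are PELP1 shRNA over control shRNA and are given with the standard error (SE). Levels are TMM-scaled CPM values, read counts brought to a common library size, with the standard deviation (SD) over 2 libraries. Differences were also tested against a 1.5-fold change with glmTreat. The labels name a DESeq pipeline, and DESeq2 1.42.0 was run as an alternative.

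Both pairs of replicates differed by more than counting noise, so each library counted as a sample. Over genes with a summed count of at least 10, chi-square per degree of freedom was 2.469 for the control pair and 2.374 for the PELP1 shRNA pair, against 56.13 to 61.96 between groups. The labels do not say whether the duplicates came from separate cultures. All p-values therefore measure only the spread between these libraries, which may be technical. The biological coefficient of variation estimated from them was 2.99%.

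Before the data were examined, 25 gene lists were fixed, and 24 of them had members to test. The 25th held the mitochondrially encoded genes. Each list was tested against the other genes with camera in limma 3.58.1, first with a preset correlation of 0.01 and then with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. fry tested whether the genes of a list moved, on balance, in one direction, without comparing them with other genes. With the estimated correlation no list passed, and the lowest adjusted p was 0.212. That form takes its degrees of freedom from the 4 libraries alone, so its power is low. Cholesterol biosynthesis genes missed the threshold there with an estimated correlation of −0.0364, below the preset one. A miss therefore does not show that correlation between genes accounts for the shift of a list. A list planted in simulated counts did pass in that form (camera adjusted p = 0.0166). Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

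Genes were named by a rule fixed at the same time. It took PELP1 and the 8 genes with the largest change in each direction among those past the FDR threshold, with a mean of at least 5 CPM and no overlap between the groups. Non-coding and pseudogene symbols were skipped. It added up to 3 members of each list with the largest change past the threshold. The partners of PELP1 (TEX10, WDR18, SENP3, LAS1L, NOL9 and MDN1) and RELA, NFKB1, GLI1, GLI2 and MKI67 were named in any case. Genes named outside the rule are said to have been chosen after their values were seen.

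Coordinates, exon overlaps, gene lengths and 3′ UTRs came from the GENCODE annotation of GRCh37, the assembly behind hg19. Of the 23228 gene rows, 19137 matched it by symbol and 2188 by an older symbol. Every 7-mer found in at least 100 and missing from at least 100 of 10958 annotated 3′ UTRs was compared between genes with and without it, over genes with a mean of at least 5 CPM. On simulated data this scan recovered 10 of 10 planted 7-mers with a shift of 0.3 on the log2 scale. The leading 7-mer of the real data had a smaller shift, with medians of −0.0959 with it and −0.0103 without it. Recovery at that size was not tested. The strongest z without a planted shift was −4.83.

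The gene test was also tested on simulated counts for the comparison of PELP1 shRNA with control shRNA, run on 14845 genes. It recovered 42% of 50 genes changed 1.2-fold, 80% of those changed 1.5-fold, 94% of those changed 2-fold and 96% of those changed 4-fold. Of 165 genes called, 9 had not been changed. Only 200 genes were changed, while 58.1% of tested genes were called in the real data. The counts were drawn with the dispersions estimated from these same libraries. These rates therefore need not hold for the real comparison. A list planted with a shift of −0.5 was called and 0 of the 23 other lists were. The simulated genes were drawn independently of one another, so this does not show how often lists of correlated genes are called wrongly.

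The alternatives were scaling with DESeq2 size factors, upper-quartile factors or library size alone, the DESeq2 Wald test, limma-voom, edgeR without robust dispersion, no low-count filter, a filter of at least 5 CPM in 2 libraries, leaving out each library, a block for the replicate number and the test against a 1.5-fold change. A crossed replicate block and an assumed biological variation of 10% or 20% were added after the data were seen.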

Results

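Gene expression was measured by RNA sequencing in Daoy cells, a human medulloblastoma line, stably expressing a control shRNA (n = 2 libraries) or an shRNA against PELP1 (n = 2 libraries). PELP1 is a scaffold protein that acts as a coregulator of nuclear receptors and is a member of a nucleolar complex needed for ribosome maturation. The deposited values were raw counts per gene, from 24052542 to 29221640 counts in genes per library. The only comparison was PELP1 shRNA against control shRNA. The title of the series frames it as a question about the NF-κB pathway and medulloblastoma progression.

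PELP1 transcripts fell to 29.8% of the control level. The level was 176.7 ± 12 CPM (SD, n = 2) with the control shRNA and 52.64 ± 4.15 CPM (SD, n = 2) with the PELP1 shRNA, a log2 fold change of −1.75 ± 0.05 (SE; edgeR quasi-likelihood test, FDR = 1.54e-33). Individual control libraries held 168.2 and 185.2 CPM, and the PELP1 shRNA libraries 55.6 and 49.7 CPM. PELP1 lies on the minus strand of chromosome 17 (hg19, 4573069 to 4607632), and 284 of its exonic bases overlap antisense transcripts. Its partners changed far less. NOL9, a polynucleotide kinase of ribosomal RNA processing, fell (log2 fold change −0.56 ± 0.07, SE, FDR = 4.82e-11), as did TEX10 (−0.26 ± 0.05, SE, FDR = 2.52e-06). The SUMO protease gene SENP3 rose by 0.23 ± 0.07 (SE, FDR = 0.00569) and MDN1, an ATPase of ribosome assembly, fell by 0.13 ± 0.06 (SE, FDR = 0.0414). SENP3 missed the threshold without PELP1 shRNA replicate 2 (adjusted p = 0.0871) and with DESeq2 (adjusted p = 0.07). MDN1 missed it without PELP1 shRNA replicate 2 (adjusted p = 0.368) or control replicate 1 (0.199), with upper-quartile factors (0.241), library size alone (0.567) and DESeq2 (0.178), with the replicate block (0.0787), and with no low-count filter (0.0569) or the filter at 5 CPM (0.0697). With an assumed biological variation of 10%, chosen after the data were seen, TEX10 (adjusted p = 0.181), SENP3 (0.27) and MDN1 (0.562) missed the threshold. At 20% NOL9 missed it as well (adjusted p = 0.306). SENP3 shares 1511 exonic bases with a gene on the same strand. WDR18 (0.0066, FDR = 0.919) and LAS1L (−0.0795, FDR = 0.187) did not pass the threshold.

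**Figure D1:**
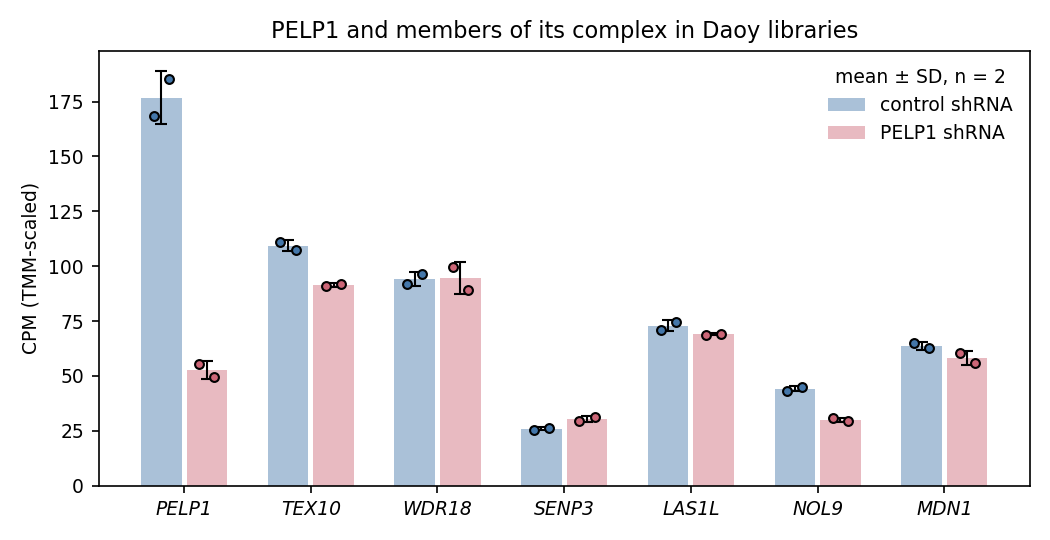
Expression of PELP1 and 6 members of its complex in TMM-scaled CPM (y axis), for control shRNA (blue) and PELP1 shRNA (red). Bars are means, error bars the SD and points the 2 libraries of each group; PELP1 lay at 176.7 CPM with the control shRNA and 52.64 CPM with the PELP1 shRNA.

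Of 14972 genes tested, 8700 (58.1%) passed the FDR threshold in the edgeR test, 4276 higher and 4424 lower with the PELP1 shRNA. Scaled by library size alone, 5681 genes were higher and 3305 lower, so that the share of higher calls was 63.2% in place of 49.1%. Most differences were small, with a median absolute log2 fold change of 0.40 among called genes and a change below 1.5-fold in 5922 of them. At least 2-fold changes were seen in 705 higher and 556 lower genes. With the filter of at least 5 CPM in 2 libraries, 248 higher and 261 lower genes changed that much. Tested against a 1.5-fold change, 1442 genes passed, 709 higher and 733 lower. Under an assumed biological variation of 20%, an alternative chosen after the data were seen, 1325 genes passed.

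The strongest rise among the named genes was that of DMBT1, which encodes a secreted scavenger receptor glycoprotein and lies on chromosome 10 (124320181 to 124403252). It had 3 and 1 counts in the control libraries and 777 and 714 in the PELP1 shRNA libraries, a ratio of 317 (95% counting interval 124 to 1170). Its fitted log2 fold change of 8.23 moved to 9.22 without control replicate 1 and to 7.60 without control replicate 2. GSTO2, an omega-class glutathione transferase, rose 16.8-fold, from 0.96 ± 0.04 to 16.1 ± 0.12 CPM (SD, n = 2), and AFF2, the gene of the FRAXE fragile site, rose 12.7-fold. WISP1, a matricellular protein of the CCN family, rose 7.71-fold. MYEOV rose 7.34-fold and MCTP2 6.31-fold. PKIB, an inhibitor of protein kinase A, rose 5.91-fold, and MAT1A, a methionine adenosyltransferase of the liver, 5.65-fold. FDR values of these 8 genes were at most 8.61e-23.

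The largest named fall was that of NAA11, the catalytic subunit of an N-terminal acetyltransferase, on chromosome 4 (80146848 to 80247215). It fell from 14.1 ± 0.45 to 0.40 ± 0.15 CPM (SD, n = 2), a log2 fold change of −5.13 ± 0.20 (SE, FDR = 1.19e-32). Several of the other genes encode matrix proteins or matrix proteases. COL1A2, the α2 chain of type I collagen on chromosome 7 (94024207 to 94060539), fell from 1495 ± 40.0 to 131.9 ± 10.0 CPM (SD, n = 2; log2 fold change −3.50 ± 0.04, SE, FDR = 3.99e-54). The small proteoglycan gene BGN fell by 3.6, the aggrecanase gene ADAMTS5 by 3.50 and ADAMTS1 fell by 3.23 on the log2 scale. DKK1, a secreted Wnt antagonist, fell by 3.36 and the activin-binding protein gene FST by 3.02. CCDC152 fell by 3.54, and 1452 of its exonic bases lie antisense to the selenoprotein P gene. The highest FDR among these 8 genes was 1.75e-25.

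**Figure D2:**
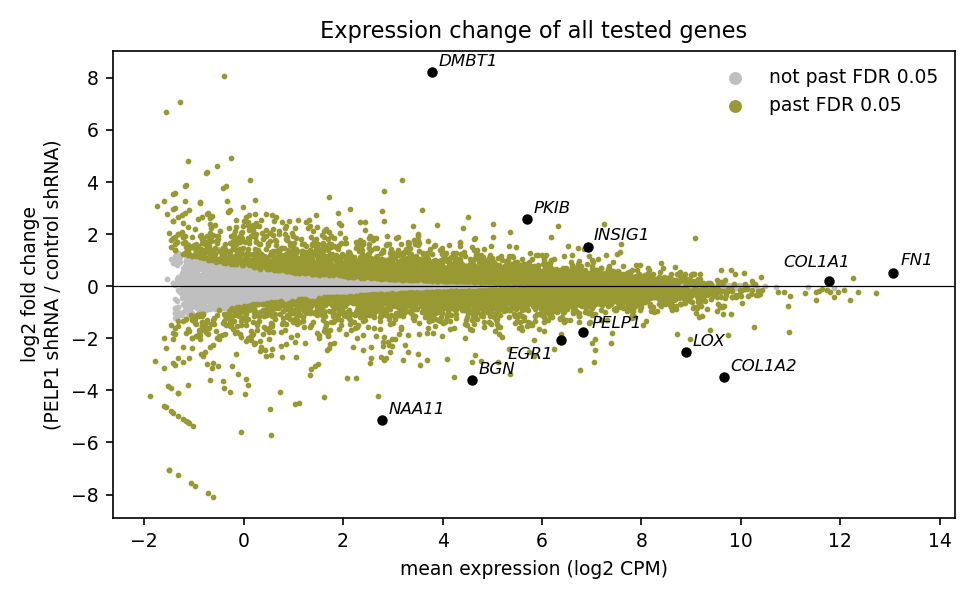
Log2 fold change of PELP1 shRNA over control shRNA (y axis) against mean expression in log2 CPM (x axis) for the 14972 genes tested. Each point is a gene, coloured by whether it passed FDR 0.05; black points mark 11 genes, among them PELP1 at −1.75, COL1A2 at −3.50 and DMBT1 at 8.23.

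Genes of the NF-κB pathway moved in both directions. Of 34 tested NF-κB target genes, 10 rose, 16 fell and 8 did not pass, with a median log2 fold change of −0.11. The list did not stand apart from other genes (camera adjusted p = 0.254, or 0.465 with an estimated correlation). Its members were lower on balance (fry adjusted p = 0.00781). The same held for integrins (fry adjusted p = 0.0164), hedgehog genes (0.0183) and oestrogen-responsive genes (0.00822), so it was not particular to this list. With library size alone, 12 target genes rose and 13 fell, with a median of −0.0204. The gelatinase gene MMP9 fell by 3.40 ± 0.25 (SE, FDR = 1.27e-18), from 4.81 to 0.45 CPM. The BCL2 family member BCL2A1 fell by 2.10 and the chemokine gene CCL5 by 1.92, both from under 2 CPM, and CCL5 stood at −2.82 without PELP1 shRNA replicate 1. NFKB1, which encodes the p105 precursor, fell by 0.19 ± 0.06 (SE, FDR = 0.00667). That call was lost with upper-quartile factors (adjusted p = 0.0532), library size alone (−0.0954, adjusted p = 0.169) and DESeq2 (adjusted p = 0.0643). It was also lost without PELP1 shRNA replicate 2 (log2 fold change −0.139) or control replicate 1 (−0.161). With an assumed biological variation of 10%, chosen after the data were seen, the adjusted p was 0.377. RELA, the p65 subunit, stood at 0.08 ± 0.05 (SE, FDR = 0.121), and at 0.13 with an adjusted p of 0.0337 without control replicate 2. It was called higher with upper-quartile factors (0.134, adjusted p = 0.00866), library size alone (0.171, adjusted p = 0.000645) and the crossed replicate block, chosen after the data were seen (adjusted p = 0.0375). Of 30 NF-κB pathway components, 6 rose, 16 fell and 8 did not pass (median −0.14, camera adjusted p = 0.311). With library size alone, 9 components rose and 9 fell, with a median of −0.0483, so the balance of calls depended on scaling. TLR4, the lipopolysaccharide receptor, had 38 counts in the control libraries together and 3 in the PELP1 shRNA libraries, 14.9-fold fewer (95% counting interval 4.73 to 75.4). The receptor gene TNFRSF1B fell by 1.14 and MAP3K14, the kinase of the non-canonical pathway, by 1.00 on the log2 scale. MAP3K14 shares 858 exonic bases with an antisense gene. Adjusted over the list alone, the target counts were the same and the component counts were 7 higher and 17 lower.

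Cytokine and growth factor ligand genes were lower as a list (29 tested, 6 higher, 16 lower, 7 not past the threshold, median −0.42). The camera adjusted p was 0.00159, and adjusted p = 0.255 with an estimated correlation. IL11 fell from 62.9 ± 2.55 to 8.42 ± 0.52 CPM (SD, n = 2; FDR = 2.73e-41) and VEGFC, a lymphangiogenic growth factor, fell by 1.92 on the log2 scale. GDF15, a stress-induced ligand of the TGF-β superfamily, rose 4-fold. When adjusted over the list alone, 6 rose and 17 fell.

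Both extracellular matrix lists were lower with the PELP1 shRNA. Of 44 structural genes, 27 fell, 12 rose and 5 did not pass, with a median log2 fold change of −0.48 (camera adjusted p = 4.93e-20; adjusted p = 0.255 with an estimated correlation). Of 32 remodelling genes, 24 fell, 5 rose and 3 did not pass, with a median of −0.59 (camera adjusted p = 2.77e-23; adjusted p = 0.212 with an estimated correlation). Adjusted over the list alone, 28 structural genes fell and the other counts were the same. Besides COL1A2 and BGN, POSTN (periostin) fell by 3.52, from 8.21 to 0.71 CPM. LOX, the collagen cross-linking lysyl oxidase, fell by 2.54 ± 0.04 (SE, FDR = 1.75e-55), from 816.8 ± 13.6 to 140.4 ± 1.57 CPM (SD, n = 2). The most abundant matrix genes did not all fall. Among the 10 with the highest control level, looked at after the data were seen, FN1 rose by 0.51 ± 0.03 (SE), THBS1 by 0.32 ± 0.03 (SE) and COL1A1 by 0.18 ± 0.04 (SE). The other 7 fell, among them COL6A2 (−1.86), COL6A1 (−1.56) and LAMB1 (−1.06). Integrins and adhesion receptors did not stand apart as a list (29 tested, 9 higher, 17 lower, median −0.21, camera adjusted p = 0.28), with the same counts when adjusted over the list alone. ALCAM fell from 310.9 ± 1.82 to 139.3 ± 3.35 CPM (SD, n = 2). The low-abundance genes CDH6 and ITGB2 fell by 2.69 and 1.83 on the log2 scale, and without PELP1 shRNA replicate 1 stood at −3.57 and −2.56. CDH6 had 45 counts in the control libraries together and 8 in the PELP1 shRNA libraries.

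Most immediate early genes fell. Of 30 tested, 21 were lower and 6 higher (median −0.56, camera adjusted p = 4.52e-10; adjusted p = 0.262 with an estimated correlation). EGR1 fell from 137.8 ± 6.13 to 32.7 ± 2.00 CPM (SD, n = 2), CYR61 from 1021 ± 10.3 to 321.6 ± 5.68 CPM (SD, n = 2) and JUN by 1.17 on the log2 scale. Interferon-stimulated genes were lower as well, with 24 of 35 lower and 2 higher (median −0.48, camera adjusted p = 8.34e-05; adjusted p = 0.255 with an estimated correlation). OASL fell by 2.25 and IFIT2 by 1.80 on the log2 scale, and the antiviral gene RSAD2 fell by 1.99 from 1.66 ± 0.18 CPM (SD, n = 2). Unfolded protein and integrated stress response genes were lower in 18 and higher in 2 of 30 cases (median −0.20, camera adjusted p = 0.00409; adjusted p = 0.255 with an estimated correlation). SLC7A11, the cystine transporter, fell by 1.15 and PPP1R15A, the eIF2α phosphatase subunit, by 1.01, while the mTORC1 inhibitor gene DDIT4 rose by 1.09. Of 29 hypoxia and glycolysis genes, 17 were lower and 5 higher (median −0.21, camera adjusted p = 0.0177; adjusted p = 0.262 with an estimated correlation). Hexokinase gene HK1 fell from 180.9 ± 2.26 to 69.9 ± 1.21 CPM (SD, n = 2), VLDLR fell by 0.57 on the log2 scale and the aldolase gene ALDOC rose by 1.14. Adjusted over the list alone, 4 interferon-stimulated genes rose and 25 fell, and the counts of the other 3 lists were the same.

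Cholesterol biosynthesis genes rose together. Of 25 tested, 22 rose, 0 fell and 3 did not pass, with a median of 0.47 (camera adjusted p = 9.4e-13; adjusted p = 0.212 with an estimated correlation), and counts were the same when adjusted over the list alone. At an unadjusted p of 0.05 the count of lower genes was 0 in edgeR, and DESeq2 and limma-voom also called 0 lower. INSIG1, the sterol-regulated retention factor of SREBP, rose from 61.9 ± 0.17 to 177.5 ± 0.72 CPM (SD, n = 2). The reductase genes TM7SF2 and DHCR7 rose 3.6-fold and 2.07-fold. Epithelial markers were also higher, at low levels. Of 15 tested, 9 rose and 2 fell, with a median of 0.86 (camera adjusted p = 0.00235; adjusted p = 0.255 with an estimated correlation). The median member had 2.20 CPM, and 10 rose and 2 fell when adjusted over the list alone. The transcription factor gene ELF3 rose 5.32-fold to 5.98 ± 0.16 CPM (SD, n = 2) and the splicing regulator gene ESRP1 3.75-fold to 4.52 ± 0.13 CPM (SD, n = 2). EPCAM stood at 0.25 and 0.78 CPM (FDR = 0.00222), a call lost without control replicate 2 (adjusted p = 0.142). Without control replicate 1 its log2 fold change moved from 1.65 to 2.69.

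Genes of ribosome assembly and ribosomal proteins were slightly lower. Among 35 genes of the PELP1 complex and ribosome biogenesis, 20 fell, 2 rose and 13 did not pass, with a median of −0.15 (camera adjusted p = 0.0286; adjusted p = 0.27 with an estimated correlation). The list missed the threshold with upper-quartile factors (adjusted p = 0.0704) and with library size alone (adjusted p = 0.107). BOP1, a factor of large subunit assembly, fell from 8.40 ± 0.32 to 4.10 ± 0.88 CPM (SD, n = 2), RRP9 fell by 0.59 and WDR43 by 0.56 on the log2 scale. Of 76 cytosolic ribosomal protein genes, 49 fell, 0 rose and 27 did not pass, with a median of −0.19 (camera adjusted p = 6.15e-05; adjusted p = 0.262 with an estimated correlation). DESeq2 also called 0 higher and limma-voom 1, edgeR had 1 higher at an unadjusted p under 0.05, and scaling by library size alone called 6 higher and 36 lower. RPL12, RPS2 and RPL35 fell to 65.3%, 65.4% and 66.2% of control. Ribosomal protein genes share reads with many pseudogenes, so their counts are partial. Adjusted over the list alone, 51 ribosomal protein genes fell, and the counts of the other list were the same.

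Cell cycle, p53 and apoptosis genes moved in both directions. Of 35 G2/M and mitosis genes, 17 rose and 7 fell (median 0.08, camera adjusted p = 0.254), with CDC25B at 0.42, PLK1 at −0.46 and the cytokinesis gene ANLN at −0.42. MKI67 stood at 0.05 ± 0.03 (SE, FDR = 0.241) and was called higher with upper-quartile factors (0.1, adjusted p = 0.00982) and library size alone (0.137, adjusted p = 0.000291). Of 35 DNA replication and G1/S genes, 10 rose and 13 fell, with MCM3 at 0.49, ORC6 at −0.54 and CDC45 at −0.48. The median of that list was −0.04, while camera placed it higher (adjusted p = 0.901), and the median was positive with upper-quartile factors or library size alone. Of 28 p53 target genes, 11 rose and 9 fell (median 0.10, mean −0.02, camera adjusted p = 0.922). GADD45A fell from 72.3 ± 0.82 to 24.7 ± 2.07 CPM (SD, n = 2), the death receptor gene FAS fell by 1.2 on the log2 scale and the antiproliferative gene BTG2 rose by 1.30. FAS shares 1297 exonic bases with genes on the other strand. Of 27 apoptosis regulators, 9 rose and 7 fell (median −0.03, mean 0.07, camera adjusted p = 0.856), and the median was positive with upper-quartile factors or library size alone. TNF rose 2.59-fold to 4.42 CPM, and the BH3-only genes BCL2L11 and BMF rose 1.86-fold and 1.76-fold. Of 21 replication-dependent histone genes with enough counts, 7 fell and 1 rose (median −0.40, camera adjusted p = 0.28). The median member had 1.34 CPM, and the calls of the 3 members named here were lost in some alternatives. HIST1H3D fell by 1.25 on the log2 scale and missed the threshold with DESeq2 (adjusted p = 0.0514). HIST1H1E (−1.19, FDR = 0.00199) missed it without control replicate 1 (adjusted p = 0.0975) or PELP1 shRNA replicate 1 (adjusted p = 0.0506), and with DESeq2 (adjusted p = 0.0807). HIST1H2BH (1.2, FDR = 0.0252) missed it without control replicate 1 (adjusted p = 0.289), PELP1 shRNA replicate 1 (0.0748) or PELP1 shRNA replicate 2 (0.111), and with DESeq2 (0.245), and moved to 1.92 without control replicate 2. Counts adjusted over the list alone were the same for these 5 lists.

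Neither hedgehog nor oestrogen-responsive genes stood apart as lists. Of 20 hedgehog pathway genes, 6 rose and 7 fell (median −0.07, camera adjusted p = 0.212), and the median was positive with library size alone. HHIP, a hedgehog-binding antagonist, fell from 20.4 ± 0.89 to 3.34 ± 0.62 CPM (SD, n = 2), and 813 of its exonic bases lie antisense to another gene. GLI2 fell by 0.71 ± 0.07 (SE, FDR = 2.16e-13). It did not pass against a 1.5-fold change (glmTreat adjusted p = 0.107) or with an assumed biological variation of 20% (adjusted p = 0.128). MYCN rose by 1.64 at 0.32 to 1.03 CPM, and by 2.23 without control replicate 2. GLI1 stood at 0.80 ± 0.33 (SE, FDR = 0.0332). Its call was lost without control replicate 1 (0.42, adjusted p = 0.402), PELP1 shRNA replicate 1 (adjusted p = 0.171) or PELP1 shRNA replicate 2 (adjusted p = 0.0606), and without control replicate 2 it stood at 1.40. Of 21 oestrogen-responsive genes, 7 rose and 11 fell. Their median was −0.24 and their mean 0.05, and camera placed them lower (adjusted p = 0.254). IL1RAP rose 2.25-fold to 34.6 ± 0.33 CPM (SD, n = 2). The oestrogen receptor gene ESR1 rose by 1.75 on the log2 scale, to 1.17 ± 0.32 CPM (SD, n = 2). The progesterone receptor gene PGR had 3 counts in the control libraries together and 26 in the PELP1 shRNA libraries, a ratio of 7.37 (95% counting interval 2.26 to 38). Its fitted log2 fold change of 2.79 moved to 3.39 without control replicate 1, and its call was lost with DESeq2 (adjusted p = 0.0558). Counts were the same when adjusted over the list alone.

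Markers of other cell types gave no single direction. Of 15 neuronal markers, 8 rose and 4 fell (median 0.30, camera adjusted p = 0.642), with the synaptic gene SNAP25 up 5.16-fold to 6.14 ± 0.71 CPM (SD, n = 2). NEFM (1.54, FDR = 0.00282) missed the threshold without control replicate 2 (adjusted p = 0.0567). STMN2 (−1.06, FDR = 0.0344) missed it whichever library was left out, with adjusted p from 0.0514 (without PELP1 shRNA replicate 2) to 0.239 (without PELP1 shRNA replicate 1), 0.206 without control replicate 1 and 0.0755 without control replicate 2. Of 18 glial markers, 7 rose and 5 fell. Their median was 0.05 and their mean −0.12, and camera placed them lower (adjusted p = 0.146). Without control replicate 2 that p was 0.0479. The proteoglycan gene CSPG4 fell from 130 ± 4.45 to 24.6 ± 2.20 CPM (SD, n = 2), PDGFRA fell by 2.21 on the log2 scale and MBP rose 3.04-fold. Of 8 immune cell markers, 1 fell and 0 rose, with a median of −0.07, while camera placed them higher (adjusted p = 0.901). DESeq2 and limma-voom called 0 higher, and edgeR had 1 at an unadjusted p under 0.05. LYZ, the marker that fell (−1.35, FDR = 0.0422), missed the threshold without control replicate 1 (−0.11, adjusted p = 0.906) or PELP1 shRNA replicate 2 (adjusted p = 0.175), and stood at −2.06 without control replicate 2 and −1.99 without PELP1 shRNA replicate 1. No immune marker passed (0 of 8) when adjusted over the list alone, and the counts of the neuronal and glial lists were the same.

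**Figure D3:**
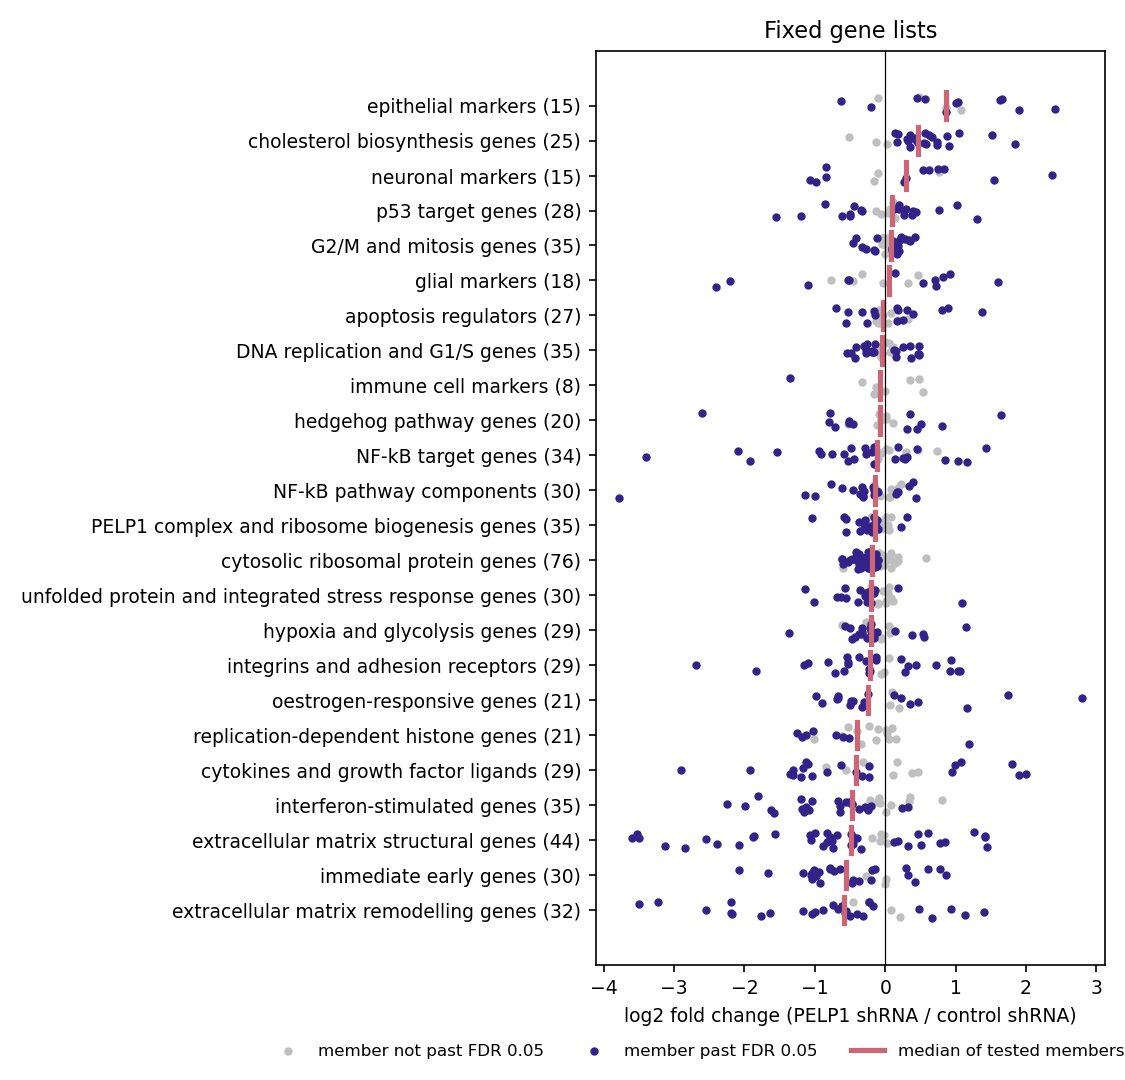
Log2 fold change of PELP1 shRNA over control shRNA (x axis) for the tested members of 24 gene lists, with the number tested in brackets. Each point is a gene, dark where it passed FDR 0.05, and red bars are medians, from −0.59 for matrix remodelling genes to 0.86 for epithelial markers; the medians of the G1/S, apoptosis, hedgehog and immune lists change sign under library-size scaling.

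A short mRNA sequence, found by a scan of 3′ UTRs, went with lower expression. Among 15790 7-mers, TGACCTA had the most negative shift between genes with and without it in their 3′ UTR (z = −7.42, Bonferroni-adjusted p = 1.85e-09), followed by the overlapping ATGACCT (z = −6.45) and the AU-rich TATTTAT (z = −6.40). The union of the first 2, the 8-mer ATGACCTA, occurs in 1 copy in the PELP1 mRNA. The 237 genes with the 8-mer in their 3′ UTR had a median log2 fold change of −0.15 (95% bootstrap interval −0.20 to −0.09). The median was −0.07 for the 1536 genes with a 7-mer but no 8-mer. It was −0.0114 for 2673 genes with only the central 6-mer of the 8-mer and −0.0028 for the 6512 genes with none of these. Of the 237, 119 (50.2%) were called lower and 53 (22.4%) higher, against 32.1% and 30.7% of the 6512. The 8-mer was put together from 7-mers chosen for their shift, so these values are not a test of it. The shift was not confined to the 3′ UTR. In 205 genes with the 8-mer upstream of the 3′ UTR and neither 7-mer in it, the median was −0.137 (95% bootstrap interval −0.178 to −0.0686), a comparison made after the data were seen. Among genes named by rule, the 8-mer was present in the 3′ UTR of ADAMTS5, HK1 and SLC7A11, which fell. PELP1 itself, COL1A2, DKK1, MAP3K14, NFKB1, FAS, IFIT2, VLDLR, ANLN and CDC45 carried a 7-mer, as did MCTP2 and WISP1, which rose.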

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

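PELP1 kept its direction and its side of the threshold in 17 of 17 alternatives, with log2 fold changes from −1.83 to −1.66, and no called gene was called the opposite way in any of them. Over 92 named genes and their alternatives, 1441 of 1543 values kept direction and side, 93 lost the call, 6 gained one and 3 reversed. Of 335 list results, 321 kept both. The crossed replicate block and the assumed biological variations were chosen after the data were seen. The number of called genes was from 7420 to 7757 when 1 library was left out, where the lone library of a group is assumed to vary like the other group. It was 6355 with the DESeq2 Wald test and 8621 with limma-voom. Against a 1.5-fold change 1442 genes passed (709 higher, 733 lower), as the question itself is stricter. With the biological variation assumed to be 10%, 4363 genes passed (2187 higher, 2176 lower), and with 20%, 1325 (685 higher, 640 lower), since a wider assumed spread leaves fewer calls. The filter of at least 5 CPM left 11497 genes to test, of which 7414 were called. It left 509 called genes with a 2-fold change, in place of 1261. Many 2-fold changes therefore lay in genes of low abundance. The low-count filter of the main test left 8256 gene rows untested, and whether more depth would have added calls was not examined.

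The replicate block gave 8161 called genes, 4010 higher and 4151 lower. Deviations of same-numbered libraries correlated at 0.0109 over all tested genes and at −0.194 over the 8831 genes with a mean log2 CPM above 4, so the numbers were not taken to pair the samples. The crossed replicate block, which pairs control replicate 1 with PELP1 shRNA replicate 2, called 9284 genes, against 8700 without a block. With the negative correlation, this leaves open a structure shared by differently numbered libraries, which the main model did not include.

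For lists, values are camera adjusted p. The PELP1 complex and ribosome biogenesis list missed the threshold with upper-quartile factors (0.0704), library size alone (0.107) and the filter at 5 CPM (0.0857). Glial markers passed with DESeq2 statistics (0.0429) and that filter (0.0212), and gave 0.0479 to 0.436 with 1 library left out. Directions reversed for immune markers with upper-quartile factors (0.979) and library size alone (0.882), for G1/S genes with limma-voom (0.902), no filter (0.814) and the crossed block (0.936), and, with 1 library left out, for immune markers (0.453 to 0.861) and p53 targets (0.874 to 0.934). LAS1L reversed with library size alone (log2 fold change 0.0106), and WDR18 gave −0.0734 to 0.0801 with 1 library left out. With DESeq2 the calls of EPCAM (adjusted p = 0.0959), GLI1 (0.27), LYZ (0.131), NEFM (0.101) and STMN2 (0.281) were lost, and STMN2 missed the threshold with library size alone (0.0513) and no filter (0.0527). Except for the scaling of LAS1L, the cause was not tested. The list test has no form against a 1.5-fold change and was not run under an assumed variation.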

Other observations

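Tests of the matrix-producing subpopulation, of ribosomal protein pseudogenes, of YAP targets, of sites in the 3′ UTR alone, of site length and of small nucleolar RNA genes against their hosts, and the 3 gene groups in the next paragraph, were chosen only after results had been seen. The other tests were written down before their result was seen.

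Transcripts of most genes in a group of fatty acid synthesis and related lipid genes, among them TMEM97, PNPLA3, GPAM and LPIN1, were higher with the PELP1 shRNA. Of 18 genes, 11 rose and 3 fell, with a median log2 fold change of 0.39 (camera adjusted p over 4 added groups = 1.41e-07; adjusted p = 0.0708 with an estimated correlation). SREBF1, the transcription factor of the pathway, rose by 1.89 ± 0.06 (SE), and the desaturase genes FADS2 and SCD by 1.19 and 0.90. ELOVL6 fell by 0.82 and ACLY by 0.12. Among 15 tested claudin and keratin genes outside the epithelial list, 7 rose and 2 fell (median 0.43, adjusted p = 0.00431; adjusted p = 0.0929 with an estimated correlation). CLDN1 rose by 1.04, CLDN11 by 1.18 and KRT80 by 1.22, while CLDN12 fell by 0.65. Of 37 proteasome subunit genes, 22 fell and 1 rose (median −0.18, adjusted p = 0.000231; adjusted p = 0.0874 with an estimated correlation), with PSMB5 at −1.10 and PSMB2 at −0.69. Against 10000 random lists matched on mean expression, the fatty acid and the claudin and keratin medians lay above the central 95% (upper limits 0.115 and 0.352), while the proteasome median lay inside it (−0.183 to 0.0296). None of the 4 medians, that of the YAP list below included, changed sign under upper-quartile or library-size scaling, where the proteasome median was −0.13 and −0.0888.

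Published target genes of YAP, a growth-control coactivator that works with TEAD factors, were lower. Of 22 signature genes, recalled from the literature without a copy at hand, 18 fell and 3 rose. Their median of −0.754 lay below the 2.5th percentile (−0.211) of 10000 random lists matched on mean expression, and adjusted p = 0.054 with an estimated correlation. F3 fell by 2.91, CRIM1 by 1.48, IGFBP3 by 1.37 and AXL by 1.03, while TGFB2 rose by 0.99. For the 18 members on no list fixed beforehand the median was −0.571. It was also −0.571 without the 4 members whose 3′ UTR carries TGACCTA or ATGACCT, CRIM1 among them. YAP1 fell by 0.55 ± 0.04 (SE) and its paralog WWTR1 by 0.62 ± 0.04 (SE), and TEAD1 rose by 0.15. A hypothesis is that YAP output was lower with the PELP1 shRNA, but several members had been seen to fall before the signature was chosen. Nuclear YAP protein or TEAD reporter activity, which would decide it, was not measured here.

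The first pattern weighed is the 3′ UTR 7-mer. The z of TGACCTA was −7.42, against 3.86 for the most positive 7-mer, and it lies in the PELP1 mRNA, as 22.9% of tested 7-mers do. Site length was compared upstream of the 3′ UTR, a part the 7-mers were not chosen from. Genes with the 8-mer there lay −0.0722 (bootstrap spread 0.032) from those with a 7-mer only, while the reverse complement of TGACCTA, which a DNA element would share, had a z of −0.532. Pairing at sites in the 3′ UTR alone is argued against, since 205 genes with the 8-mer upstream of the 3′ UTR and neither leading 7-mer (TGACCTA, ATGACCT) in it had a median of −0.137, close to the −0.151 of 3′ UTR carriers. Their z was −5.38 with length, GC content and mean expression held constant, against −2.8 to 4.2 for 1022 8-mers made of the same bases in another order. A hypothesis that these values leave possible is that the PELP1 shRNA also acted on other transcripts through its seed, at sites along the whole mRNA. The shRNA sequence was not analysed here, TATTTAT (z = −6.40) passed the Bonferroni threshold without lying in the PELP1 mRNA, and an effect of PELP1 itself stays open, as does an indirect route, since the 3′ UTRs of YAP1 and WWTR1 carry a 7-mer too, as does that of TEAD2. TEAD1 carries the full 8-mer and rose, against the trend.

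The second pattern is the fall of matrix genes. With the trend on GC content and gene length removed, the median of the 76 tested matrix genes was −0.554 against −0.564 before, which argues against that bias. Matrix genes lacking TGACCTA in the 3′ UTR had a median of −0.463, and the 11 carriers lay at −0.832. Genes lacking both leading 7-mers there had medians of −0.462 (structural list) and −0.571 (remodelling list). These values argue against direct pairing in their own 3′ UTRs as the whole cause. They cannot address pairing in the transcript of a regulator. With sites along the whole mRNA counted, the 41 genes lacking both leading 7-mers had a median of −0.343 (bootstrap spread 0.14) and the 35 carriers −0.779, which leaves pairing at those sites open. Loss of a matrix-producing part of the culture should lower abundant matrix genes together, yet 3 of the 10 most abundant rose, with COL1A1 and COL1A2 moving apart. That argues against loss of cells that make all of them as the only change, though the rule was set after these values were seen. A loss masked by a rise in the remaining cells stays open, as does loss of cells that make only some. Direct and indirect seed effects, differences between the transduced cell populations and PELP1 itself stay open, since the shRNA and the population cannot be separated in this design.

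The third pattern is the fall of small nucleolar RNA and ribosomal protein genes. Of 105 small nucleolar RNA genes tested, 30 fell and 0 rose in edgeR (median −0.586). Their mean levels were low, from 0.302 to 5.79 CPM. DESeq2 called 0 and limma-voom 0 higher, and edgeR had 0 higher at an unadjusted p under 0.05. The 39 tested host genes, found for 54 of the 105, had a median of −0.251 and other genes under 500 nt one of −0.198 (spread 0.13), or −0.0428 (spread 0.16) without small Cajal body RNA, histone and ribosomal protein pseudogene rows. The 54 lay −0.368 (spread 0.053) from the genes that enclose them on the same strand, taken as their hosts. Hosts were assigned by position alone, so some may not be the true ones. For the pairs as assigned, this argues against host transcript levels as the whole cause. A share of host reads, those of unspliced introns included, and length cannot be told apart from a real fall; removing the GC and length trend, to which these shortest genes contribute themselves, left −0.118. For ribosomal protein genes, other coding genes of like mRNA length had a median of −0.0246, which argues against length. Ribosomal protein genes with at most 13 named pseudogenes had a median of −0.17 (spread 0.035) and those with more −0.205 (spread 0.039). The gap is within the spread, but each gene has at least 1 named pseudogene, so shared reads stay open, and a biological fall also remains untested.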
